A study of Mus musculus with 39 samples.

How the data were processed

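Gastrocnemius muscle of C57BL/6 mice was sequenced from 5 groups: PBS, and 7, 14, 21 and 28 days of LLC tumour, called weeks 1 to 4. Per the labels' protocols, muscles were flash frozen, RNA was taken with Trizol, and libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit. Count files of 38 libraries were analysed. The labels give every sample a number of its own, so no number is shared between groups, and replicates are numbered here in the order of the series. Each library's sequencing lane was read from its file name. Ddx3y, a gene of the Y chromosome, was above 5 CPM in all 38 libraries.

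The deposited gene counts were made by the authors with FastQC, HISAT2 and HTSeq on genome build GRCm38.p5, per the submitters' processing notes, which give no versions, strand setting or annotation release. The deposited tables of the authors hold log2 fold changes with their standard errors, per the file headers, first group over second. The same tables hold a p-value and an adjusted p-value per gene, made with DESeq2 per the submitters' processing notes, for genes past an adjusted p of 0.05. These 9 tables were used to compare signs and calls and to name 10 genes missing from the table of GENCODE names used here. Apart from the numbers of genes they list, every measured value in the report comes from the counts.

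Lines of the count files that hold unassigned reads stayed out of library sizes and tests. Reads in genes numbered 13356756 to 24801565 per library, 44.5% to 80.9% of all reads. Reads in no gene made up 3.80% to 10.6%, reads over more than 1 gene 2.78% to 11.0%, and reads of more than 1 place in the genome 7.47% to 27.8%. No library duplicated another: for every pair within a group, the chi-square of the counts per degree of freedom was at least 13.0. Of the 46078 genes in the files, 45229 are in GENCODE M21, from which names, lengths and coordinates (GRCm38) were taken.

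Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr by group with a minimum count of 10 (14689 genes left), and quasi-likelihood fits of all 5 groups at once with group as the only factor. The common dispersion was 0.0769. Each week was compared with PBS and with every other week, and an F test covered any difference among the groups. A gene counts as changed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes and their standard errors come from the fit, with the error taken as the log2 fold change over the root of F. Levels are CPM of TMM-scaled libraries, as mean ± SD.

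In all, 34 gene lists were tested against PBS at each week with camera of limma 3.58.1, with a preset correlation between genes of 0.01 and adjustment over all 136 tests. Beside it stand camera with an estimated correlation, fry, and the count of members past the threshold over all genes and adjusted over the list alone. The lists cover oxidative phosphorylation, mitochondrially encoded genes, mitochondrial biogenesis, glycolysis, fatty acid use, ubiquitin ligases, proteasome, autophagy, FoxO and glucocorticoid genes, IGF-1 and mTOR, IL-6 and STAT3, interferon, endoplasmic reticulum stress, heat shock, antioxidant genes, extracellular matrix, fast fibres, slow fibres, denervation, satellite cells, myostatin, circadian clock, cell cycle and polyamines. The others are markers of neutrophils, macrophages, lymphocytes, erythroid cells, endothelium, pericytes, fibro-adipogenic cells, tendon, adipocytes and Schwann cells. For 3 lists, means over libraries were compared with exact permutation tests.

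Groups, comparisons, tests, lists and the rule for naming genes were fixed before the data were examined. For week 4 against PBS the rule takes the 10 largest rises and 10 largest falls among called genes of at least 5 CPM on average, leaving out predicted-gene names. For the other weeks against PBS and week 4 against week 3 it takes 5 of each. For each list described it takes up to 4 members of smallest p. Always named were Fbxo32, Trim63, Foxo1, Cdkn1a, Mstn, Igf1, Socs3, Stat3, Ppargc1a, Myh4, Myh7, Col1a1 and Col3a1. Some genes that the rule takes are not reported here.

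Alternatives fixed before the data were examined were other size factors (RLE, upper quartile), no low-count filter, a mean of at least 5 CPM, a term for each lane, only lanes that hold both groups, only the groups compared, DESeq2 1.42.0, limma voom with quality weights, a change of at least 1.5 times, and each library left out in turn. Added after the data were examined were a term for lane 2 against the other lanes, leaving out the lane 2 libraries, only lanes 2 and 4 with a lane term, leaving out 4 libraries of unusual read assignment, alone or with a lane 2 term, and leaving out each library in turn for the list tests. The 4 libraries are week 3 replicates 1 and 3 and week 2 replicate 6, with over 8% of reads in no gene, and week 1 replicate 7, which carries reads on mitochondrial copies. Genes of week 4 were followed at earlier weeks with separate PBS libraries for each side, since shared controls would carry chance values into both.

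The calling was tested on simulated counts at the depth of these libraries, with 200 genes changed in week 4. Their spread was the trend over expression fitted to all 5 groups, with no further spread of single genes or groups. False calls may therefore be more frequent in the real data. There edgeR recovered 37.3% of 1.5-fold, 77.6% of 2-fold and 93.9% of 4-fold changes, with 5 false among 144 calls. With the estimated lane 2 differences added, noise of the estimate included, 246 of 385 calls were false by group alone and 6 of 136 with a lane 2 term. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.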

Results

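RNA sequencing was used to follow the gastrocnemius, a calf muscle made up mainly of fast fibres, while a tumour developed in C57BL/6 mice. Lewis lung carcinoma (LLC) cells are a line derived from a mouse lung tumour. They are injected into this strain to study cancer cachexia, the loss of muscle mass that can accompany a tumour. Mice of 8 weeks of age received the cells or phosphate-buffered saline (PBS) in the flank. Tumours were given 7, 14, 21 or 28 days, here called weeks 1 to 4, and the comparisons ask how the muscle transcriptome departs from the PBS control as that time lengthens. The count files analysed here held 8 libraries of PBS, 8 of week 1, 7 of week 2, 7 of week 3 and 8 of week 4. Replicate 2 of week 3 is not analysed here. The labels number the samples separately and say no more about the animals, so the p-values measure the spread between these samples. The labels give 0 days for PBS, and the age of these mice at collection is not given in the sources used here. Age and time with a tumour cannot be separated against PBS or between weeks.

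Reads in genes numbered 13356756 to 24801565 per library, and 14689 genes had enough reads to be tested. The 4 sequencing lanes were spread unevenly over groups, and week 4 (lanes 2 and 4) shared none with PBS (lanes 5 and 6). Lane 2 held 3 libraries of week 1, 1 of week 2, 1 of week 3, 5 of week 4 and 0 of PBS. Within weeks 1 to 3, 1880 genes were lower and 1592 higher in the 5 lane 2 libraries than in the other 17 (edgeR, adjusted p under 0.05). Ribosomal protein genes were among the lower ones, with a median log2 difference of -0.88 and 71 of 91 genes past the threshold. So were nuclear genes of oxidative phosphorylation, with a median of -0.85 and 62 of 76 genes. Counts of changed genes are therefore given over all libraries, with a term for lane 2, and without the lane 2 libraries. The last 2 of these were chosen after the data were examined. PBS replicate 1 lay above the other 7 PBS libraries in macrophage markers (mean log2 CPM 5.31, against 1.92 to 3.21) and cell cycle genes (3.13, against 0.76 to 1.58). List tests were therefore repeated with each library left out, also a choice made after the data were examined.

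Over the whole course, 3219 genes differed among the 5 groups (edgeR quasi-likelihood F test, adjusted p under 0.05), and 1646 did so with a lane 2 term. Without the lane 2 libraries there were 244. In the fit over all libraries by group, week 4 differed from PBS in 4315 genes, against 9 at week 1, 0 at week 2 and 51 at week 3. Without the lane 2 libraries, with 3 left at week 4, the counts were 136 at week 4 and 95 at week 3, and 0 genes differed between these 2 weeks.

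**Figure D1:**
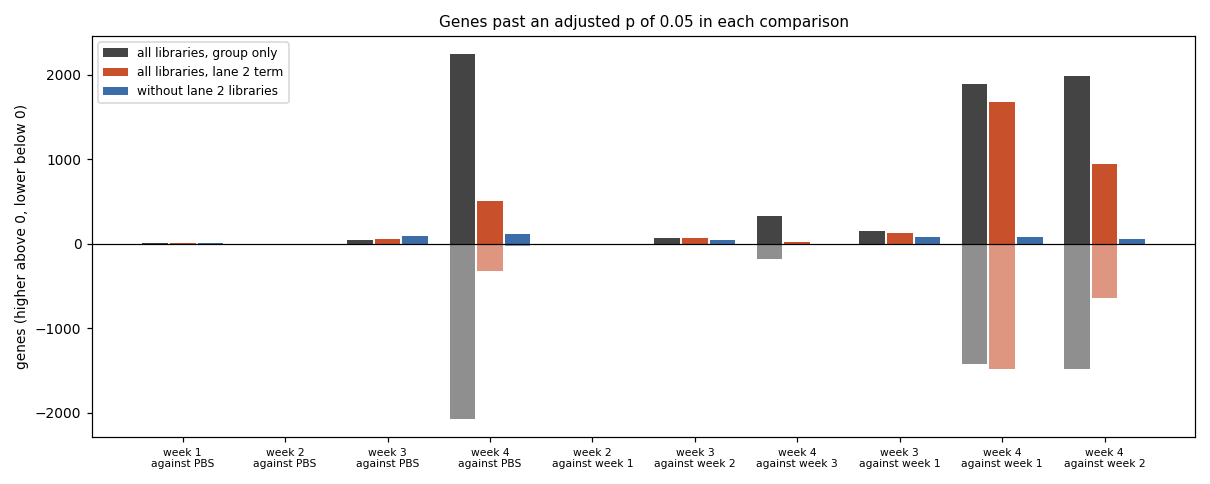
Genes past an adjusted p of 0.05 in each of the 10 comparisons, higher genes above 0 and lower genes below it, fitted over all libraries by group, with a lane 2 term, and without the lane 2 libraries. Week 4 against PBS holds 4315 genes in the first fit, 829 in the second and 136 in the last.

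At week 1 (n = 8, against 8 of PBS) few single genes differed from PBS. Csrp3, which encodes the muscle LIM protein of the sarcomere's Z-disc, fell 3.37-fold (log2 fold change -1.75 ± 0.35, adjusted p = 0.021), from 72.5 ± 31.7 to 21.5 ± 7.23 CPM (counts scaled to library size, mean ± SD), and lay below the PBS mean in 8 of 8 libraries. Its call held in 8 of 16 fits with 1 library left out. Csrp3 (ENSMUSG00000030470) lies at chromosome 7, 48830398 to 48848033 of GRCm38. Ms4a7, a membrane protein of macrophages named here after its value was seen, was called lower (-2.21, adjusted p = 0.03), but it was at -1.06 without PBS replicate 1 and the call ended. The other 7 genes were nuclear copies of mitochondrial genes, such as Gm10925 (log2 fold change 7.42), which share nearly identical sequence with their mitochondrial originals. All 7 were called on the reads of 1 library, week 1 replicate 7, and none without it. The muscle ubiquitin ligase genes did not pass the test, with Fbxo32 at -0.38 ± 0.31, adjusted p = 0.72 and Trim63 at -0.19 ± 0.40, adjusted p = 0.90.

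Among gene lists fixed before the data were examined, markers of macrophages and monocytes lay furthest below PBS at week 1 (median -1.06, adjusted p = 3.0e-07, and adjusted p = 0.64 with an estimated correlation), but without PBS replicate 1 their median was -0.20, adjusted p = 0.0088. Ctss, a lysosomal protease of macrophages, had a log2 fold change of -1.97, adjusted p = 0.19, and Tyrobp, an adaptor of their activating receptors, -1.44, adjusted p = 0.21, or -0.31 and -0.60 without that library. Of its 18 members 0 passed over all genes, and 13 were lower when adjusted over the list alone. Slow fibre genes fell (median -0.57, adjusted p = 3.1e-05, and adjusted p = 0.64 with an estimated correlation, and a median of -0.32 with a lane 2 term), with Csrp3 as the 1 member past the threshold over all genes and 2 lower adjusted over the list alone. No other member of these lists passed over all genes. Heat shock and chaperone genes fell (median -0.42, adjusted p = 1.1e-05, and adjusted p = 0.36 with an estimated correlation, and a median of -0.27 without lane 2 libraries), with Cryab, a small heat shock protein of muscle, at -0.84, adjusted p = 0.21 and 4 members lower adjusted over the list alone. Cell cycle genes were called lower (median -0.39, adjusted p = 0.0042, and adjusted p = 0.64 with an estimated correlation), with Ccna2 at -2.19, adjusted p = 0.29 and 3 lower adjusted over the list alone. So were neutrophil markers (median -0.82, adjusted p = 0.022, and adjusted p = 0.66 with an estimated correlation), with 1 lower adjusted over the list alone, and erythroid markers (median -0.72, adjusted p = 0.043, and adjusted p = 0.66 with an estimated correlation). The cell cycle median was -0.080, adjusted p = 0.30, without PBS replicate 1, with Ccna2 then at -0.85, and -0.63 without lane 2 libraries. The neutrophil list, at -0.55, adjusted p = 0.16 without it, was called in 13 of 16 fits with 1 library left out, and the erythroid list in 8 of 16, with medians from -0.86 to -0.54.

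Smaller shifts also passed at week 1. Antioxidant genes (median -0.22, adjusted p = 0.0024, and adjusted p = 0.64 with an estimated correlation) and proteasome subunits (median -0.13, adjusted p = 0.021, and adjusted p = 0.75 with an estimated correlation) fell. Schwann cell markers (median 0.33, adjusted p = 0.0027, and adjusted p = 0.66 with an estimated correlation), glycolysis genes (median 0.14, adjusted p = 0.0038, and adjusted p = 0.66 with an estimated correlation) and IGF-1, insulin and mTOR genes (median 0.13, adjusted p = 0.0042, and adjusted p = 0.60 with an estimated correlation) rose. Genes of mitochondrial biogenesis and dynamics (median 0.095, adjusted p = 0.011, and adjusted p = 0.36 with an estimated correlation) and of the circadian clock (median 0.18, adjusted p = 0.02, and adjusted p = 0.49 with an estimated correlation) rose as well. Nuclear genes of oxidative phosphorylation fell (median -0.22, adjusted p = 1.1e-05, and adjusted p = 0.67 with an estimated correlation), but with a lane 2 term their median was positive (0.11, adjusted p = 1.3e-05). In the lists of this paragraph 0 members passed over all genes and 0 adjusted over the list alone. The calls of proteasome, antioxidant, IGF-1, clock and erythroid lists ended with a lane 2 term (medians -0.038, -0.13, 0.026, 0.13 and -0.58, adjusted p = 0.68, 0.12, 0.12, 0.079 and 0.079). Without lane 2 libraries the proteasome, clock and erythroid calls also ended, at medians of -0.065, 0.12 and -0.56. So did those of oxidative phosphorylation (0.018, adjusted p = 0.71), neutrophil (-0.54, adjusted p = 0.056) and Schwann cell lists (0.13, adjusted p = 0.12), and that of mitochondrial biogenesis at a nearly unchanged median (0.090, adjusted p = 0.053). Without PBS replicate 1 the mitochondrial biogenesis call ended with its median at 0.089, adjusted p = 0.08, and the clock call at 0.12, adjusted p = 0.091. Medians without week 1 replicate 5 were -0.14 for oxidative phosphorylation and 0.076 for IGF-1 genes, and the Schwann cell median was 0.51 without PBS replicate 2. The remaining 20 lists did not pass (adjusted p from 0.072 to 0.90). Of these, extracellular matrix (-0.24, adjusted p = 8.6e-05), mitochondrially encoded (-0.42, adjusted p = 0.00064), endoplasmic reticulum stress (-0.14, adjusted p = 0.0055) and fast fibre genes (0.18, adjusted p = 0.01) passed with a lane 2 term, and mitochondrially encoded (-0.17, adjusted p = 1.9e-05) and endoplasmic reticulum stress genes (-0.11, adjusted p = 0.015) without lane 2 libraries. FoxO and glucocorticoid genes had a median of 0.054 and a mean of -0.073, and myostatin and activin genes 0.0078 and -0.010, with an upward test in both, and the FoxO list passed without PBS replicate 1 (0.16, adjusted p = 0.016).

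At week 1 edgeR called 9 genes, 7 higher and 2 lower, with 1274 at an unadjusted p under 0.05. There were 7 with a lane 2 term and 7 without lane 2 libraries, in both cases the 7 mitochondrial copies, and Csrp3 was then at -1.56, adjusted p = 0.12 with a lane 2 term. DESeq2 called 1, a fit with a term for every lane 0, and edgeR without week 1 replicate 7 called 0.

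At week 2 (n = 7, against 8 of PBS) 0 single genes passed the test and 10 lists were called. Of these, 3 were still called without PBS replicate 1, those of erythroid, slow fibre and FoxO genes. Markers of macrophages and monocytes were called lower (median -0.93, adjusted p = 3.6e-05, and adjusted p = 0.66 with an estimated correlation), against the same PBS libraries as at week 1, with Ctss at -1.79, adjusted p = 0.33, the lysozyme gene Lyz2 at -1.26, adjusted p = 0.34 and 13 of 18 lower adjusted over the list alone. Without PBS replicate 1 their median was -0.11, adjusted p = 0.46, with Ctss at -0.13 and Lyz2 at -0.16. Cell cycle genes were called lower (median -0.55, adjusted p = 0.0069, and adjusted p = 0.66 with an estimated correlation), with the cyclin gene Ccna2 at -3.00, adjusted p = 0.33 and 4 lower adjusted over the list alone, and had a median of -0.008, adjusted p = 0.33, without that library. Extracellular matrix genes (median -0.22, adjusted p = 0.004, and adjusted p = 0.67 with an estimated correlation), with fibrillin Fbn1 at -0.85, adjusted p = 0.42, and interferon response genes (median -0.18, adjusted p = 0.01, and adjusted p = 0.66 with an estimated correlation), with B2m, the light chain of class I molecules, at -0.50, adjusted p = 0.33, were called lower too. These were at 0.023, adjusted p = 0.61, and -0.12, adjusted p = 0.14, without it. The extracellular matrix median was -0.35 with a lane 2 term and -0.38 without lane 2 libraries. Erythroid markers fell (median -0.97, adjusted p = 0.0096, and adjusted p = 0.66 with an estimated correlation).

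Of the fibre type lists at week 2, slow fibre genes fell (median -0.37, adjusted p = 0.0057, and adjusted p = 0.66 with an estimated correlation) and fast fibre genes were called higher (median 0.22, adjusted p = 0.0045, and adjusted p = 0.66 with an estimated correlation), a call that ended without PBS replicate 1 (0.14, adjusted p = 0.066). Myh4, the heavy chain of the fastest fibres, was at 0.39 ± 0.20, adjusted p = 0.66, and Myh7, that of slow fibres, at -0.33 ± 0.32, adjusted p = 0.86. Circadian clock genes were called higher (median 0.27, adjusted p = 0.021, and adjusted p = 0.49 with an estimated correlation), but members went both ways. Per2 and Per3, of the clock's repressing arm, stood at 1.12 and 0.77, and Arntl and Clock, of its activating arm, at -1.12 and -0.58 (adjusted p = 0.33 for each). Adjusted over the list alone, 3 clock genes were higher and 3 lower. Pericyte and smooth muscle markers (median 0.10, adjusted p = 0.04, and adjusted p = 0.66 with an estimated correlation) were called slightly higher. The clock and pericyte calls ended without PBS replicate 1 at medians of 0.21, adjusted p = 0.10, and 0.068, adjusted p = 0.076, and with 1 library left out these lists were called in 10 of 15 and 6 of 15 fits. FoxO and glucocorticoid genes (median 0.14, adjusted p = 0.049, and adjusted p = 0.67 with an estimated correlation) rose slightly, and their call ended with a lane 2 term (0.13, adjusted p = 0.059). It held in 6 of 15 fits with 1 library left out, and the median was -0.031 without week 2 replicate 5. Slow fibre genes were called in 12 of 15 such fits, with a median of -0.23 without PBS replicate 5. Without lane 2 libraries the calls of FoxO (0.15, adjusted p = 0.071) and slow fibre genes (-0.23, adjusted p = 0.24) ended.

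No gene passed at week 2 with edgeR, where 1143 lay at an unadjusted p under 0.05. DESeq2 called 1 and limma voom 11, while edgeR with a lane 2 term and without lane 2 libraries called 0 and 0. In the called lists other than macrophage, cell cycle and clock, 0 members passed adjusted over the list alone. The remaining 24 lists did not pass (adjusted p from 0.057 to 0.90), among them ubiquitin genes, with a median of -0.072 and an upward test, and satellite cell genes, with a median of 0.0065 and a mean of -0.034. Of these 24, nuclear genes of oxidative phosphorylation passed as higher with a lane 2 term (0.10, adjusted p = 4.4e-05) and without lane 2 libraries (0.15, adjusted p = 4.4e-09), and tendon markers as lower (-0.71, adjusted p = 0.026, and -0.75, adjusted p = 0.0028). Glycolysis (0.11, adjusted p = 0.038) and endoplasmic reticulum stress genes (-0.14, adjusted p = 0.03) passed with the term, and fatty acid genes (0.088, adjusted p = 0.0015) without the libraries. Fbxo32 was at -0.29 ± 0.32, adjusted p = 0.88 and Trim63 at -0.19 ± 0.42, adjusted p = 0.96.

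At week 3 (n = 7, against 8 of PBS) transcripts of red blood cells and neutrophils rose in the muscle. Slc4a1, the band 3 anion exchanger of red cells, rose 42.8-fold (log2 fold change 5.42 ± 0.83, adjusted p = 0.0015), to 38.2 ± 62.6 CPM from 0.873 ± 0.593 (SD). It ranged from 0.769 to 174 CPM, with replicates 3, 4 and 8 in the PBS range. All 7 erythroid markers rose (median 2.95, adjusted p = 6.1e-09, and adjusted p = 0.38 with an estimated correlation), among them Alas2, the erythroid enzyme of haem synthesis (3.16, adjusted p = 0.0038). S100a8 and S100a9, which together form the neutrophil protein calprotectin, rose 17.4-fold and 13.6-fold (log2 4.12 ± 0.72, adjusted p = 0.0028, and 3.77 ± 0.69, adjusted p = 0.0038). Of the neutrophil list, 7 of 13 members rose, and 9 adjusted over the list alone (median 2.82, adjusted p = 9.4e-12, and adjusted p = 0.36 with an estimated correlation). Without week 3 replicate 6 the log2 fold changes were 4.13 for Slc4a1, 3.04 for S100a9 and 2.14 for Alas2, whose call ended, and the erythroid median was 1.89.

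Other leading genes of week 3 were Apol11b, an apolipoprotein L family member (4.99 ± 0.79, adjusted p = 0.0015, or 3.61 without week 3 replicate 6), and the keratin Krt80 (4.35 ± 0.91, adjusted p = 0.014). The Krt80 value rests on week 3 replicate 1, at 199 CPM, without which its log2 fold change was 0.24. Genes of the IL-6, STAT3 and acute phase list rose (median 0.60, adjusted p = 4.0e-06, and adjusted p = 0.60 with an estimated correlation). Their median was 0.26 without week 3 replicate 1. Osmr, the oncostatin M receptor subunit, was the 1 member past the threshold (0.96 ± 0.18, adjusted p = 0.0038), and 5 rose adjusted over the list alone. Stat3 itself stood at 0.49 ± 0.17, adjusted p = 0.27. The muscle ubiquitin ligases Fbxo32 (0.96 ± 0.32, adjusted p = 0.26) and Trim63 (0.67 ± 0.42, adjusted p = 0.56) did not pass.

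Proteasome subunits rose at week 3 (median 0.34, adjusted p = 1.4e-07, and adjusted p = 0.66 with an estimated correlation), with Psmd2 at 0.70, adjusted p = 0.16 and 4 higher adjusted over the list alone, and had a median of 0.11 without week 3 replicate 1. Autophagy genes (median 0.18, adjusted p = 0.0023, and adjusted p = 0.66 with an estimated correlation) and FoxO and glucocorticoid genes (median 0.33, adjusted p = 0.0042, and adjusted p = 0.66 with an estimated correlation) rose, with the translation repressor Eif4ebp1 at 1.16, adjusted p = 0.18. Endothelial markers rose (median 0.17, adjusted p = 0.0042, and adjusted p = 0.61 with an estimated correlation), with Vwf, the von Willebrand factor, at 0.57, adjusted p = 0.13 and 3 higher adjusted over the list alone, and with a median of 0.11 without week 3 replicate 8. Denervation genes rose (median 0.29, adjusted p = 0.017, and adjusted p = 0.61 with an estimated correlation), with Chrna1, an acetylcholine receptor subunit, at 0.91, adjusted p = 0.10 and 2 higher adjusted over the list alone. IGF-1, insulin and mTOR genes rose (median 0.13, adjusted p = 0.017, and adjusted p = 0.64 with an estimated correlation), 2 of them adjusted over the list alone. Leaving out 1 library of week 3 ended 4 of these calls, replicate 1 those of autophagy (median 0.097) and denervation (0.055), replicate 6 that of FoxO (0.15) and replicate 8 those of denervation and IGF-1 genes (0.070 for the latter). The denervation (0.21, adjusted p = 0.076) and IGF-1 calls (0.078, adjusted p = 0.091) ended without lane 2 libraries, and the IGF-1 median was 0.075 with a lane 2 term.

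Lower at week 3 were extracellular matrix genes (median -0.42, adjusted p = 1.0e-06, and adjusted p = 0.66 with an estimated correlation), with periostin, Postn, at -1.64, adjusted p = 0.32, or -0.049 without PBS replicate 1. Tendon markers fell (median -1.11, adjusted p = 0.0015, and adjusted p = 0.66 with an estimated correlation), with Comp, a cartilage and tendon matrix protein, at -1.65, adjusted p = 0.32, and so did fibro-adipogenic markers (median -0.36, adjusted p = 0.002, and adjusted p = 0.61 with an estimated correlation). Without PBS replicate 1 the medians were -0.12, adjusted p = 0.014, for extracellular matrix and -0.23, adjusted p = 0.015, for fibro-adipogenic genes, and the tendon median was -0.72 without PBS replicate 3. Nuclear genes of oxidative phosphorylation (median -0.24, adjusted p = 6.1e-09, and adjusted p = 0.66 with an estimated correlation) and mitochondrially encoded genes (median -0.40, adjusted p = 0.00039, and adjusted p = 0.64 with an estimated correlation) fell, with -0.67, adjusted p = 0.48 for the complex I subunit Ndufb2. The values of the oxidative phosphorylation list were -0.14 with a lane 2 term, -0.16 without lane 2 and -0.13 without week 3 replicate 1, which left the mitochondrially encoded list at -0.25. Mean log2 CPM of the mitochondrially encoded list was 10.0, 9.69 and 8.52 in week 3 replicates 1, 5 and 7. It was 9.42 in PBS replicate 2 and 12.4 to 13.4 in the other PBS libraries. Reads of more than 1 place, which stay uncounted, made up 20.3%, 23.3%, 25.5% and 25.5% in these 4 low libraries. Week 3 replicate 3, with 27.8%, was at 11.9. Whether such reads account for the fall was not tested. In the lists of this paragraph 0 members passed, over all genes or adjusted over the list alone, and this held for the autophagy and FoxO lists. The remaining 20 lists did not pass (adjusted p from 0.057 to 0.99), though in the interferon list, whose median was -0.068 and mean 0.056, Isg15 (2.28, adjusted p = 0.0032) and Rsad2 (1.94, adjusted p = 0.011) rose, the latter not without week 3 replicate 6 (1.36). Macrophage markers, with a median of -0.53, passed as higher without PBS replicate 1 (0.30, adjusted p = 0.00068), and fast fibre genes passed as lower (-0.29, adjusted p = 0.014). Fast fibre genes also passed with a lane 2 term (-0.17, adjusted p = 0.03) and without lane 2 libraries (-0.20, adjusted p = 0.011), where antioxidant genes passed too (0.18, adjusted p = 0.03). Schwann cell markers had a median of -0.013 with an upward test, and myostatin genes 0.012 with a downward one.

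In all, edgeR called 51 genes at week 3, 50 of them higher. The 1 lower gene, named after its value was seen, was the predicted gene Gm20302 (-9.63, adjusted p = 0.033), called in 7 of 11 fits that tested it with 1 library left out. The count was 56 under a lane 2 term, which held all 51, and 95 without lane 2 libraries. A term for every lane left 0 (1382 at an unadjusted p under 0.05), as did a fit of week 3 and PBS alone (0, with 1266), while DESeq2 called 120. Without week 3 replicate 6, edgeR called 12.

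At week 4 (n = 8, against 8 of PBS) genes of muscle protein breakdown rose. Fbxo32 (atrogin-1), a muscle ubiquitin ligase induced in atrophy, rose 4.00-fold, from 554 ± 136 to 2215 ± 1479.8 CPM (SD), and was above the PBS mean in 8 of 8 libraries (log2 2.00 ± 0.32, adjusted p = 5.2e-05). Trim63 (MuRF1), a ligase of sarcomere proteins, rose 4.13-fold and was above the PBS mean in 6 of 8 (2.05 ± 0.42, adjusted p = 0.00081). Foxo1, a transcription factor that drives both ligase genes, rose 2.11-fold (1.08 ± 0.30, adjusted p = 0.0083). Fbxo32 (ENSMUSG00000022358) lies at chromosome 15, 58175879 to 58214932, and Trim63 (ENSMUSG00000028834) at chromosome 4, 134315120 to 134329629. Under a lane 2 term the values were 1.92, adjusted p = 0.0018 for Fbxo32, 2.19, adjusted p = 0.0052 for Trim63 and 0.98, adjusted p = 0.069 for Foxo1. Without lane 2 libraries, with 3 left at week 4, Fbxo32 was at 1.33, adjusted p = 0.087 and Trim63 at 1.85, adjusted p = 0.034.

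The list of ubiquitin ligases and ubiquitin genes rose (median 0.24, adjusted p = 0.017, and adjusted p = 0.61 with an estimated correlation), with 7 of 20 members higher and 2 lower, or 9 and 2 adjusted over the list alone. Ubr2, a ligase of the N-degron pathway, rose (0.52, adjusted p = 0.00026), and Trim32, a ligase of muscle, fell (-0.36, adjusted p = 0.0045). The list median was 0.15, adjusted p = 0.018, with a lane 2 term, where 4 members were higher and 0 lower, and 0.088, adjusted p = 0.015, without lane 2 libraries. Proteasome subunits rose (median 0.28, adjusted p = 0.0019, and adjusted p = 0.67 with an estimated correlation), 12 of 32 and 12 adjusted over the list alone, led by Psmd1 (0.76, adjusted p = 0.00039) and Psmd11 (1.07, adjusted p = 0.0016), and their median was 0.52 with a lane 2 term and 0.17 without week 4 replicate 6. Autophagy and lysosome genes rose (median 0.21, adjusted p = 0.028, and adjusted p = 0.66 with an estimated correlation), 8 of 24 over all genes and 8 adjusted over the list alone, a list call that held in 13 of 16 fits with 1 library left out and ended without PBS replicate 1 (0.19, adjusted p = 0.059) or without week 4 replicate 5 or 6. The cargo receptor Sqstm1 led them (0.93, adjusted p = 0.0003).

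FoxO and glucocorticoid responsive genes rose (median 0.83, adjusted p = 2.0e-05, and adjusted p = 0.64 with an estimated correlation), 15 of 24 over all genes and 18 adjusted over the list alone. Zbtb16, a zinc-finger gene induced by glucocorticoids, stood at 1.31, adjusted p = 0.00039, Foxo3 at 0.75, adjusted p = 0.00064 and the clock gene Per1 at 1.34, adjusted p = 0.0039. IGF-1, insulin and mTOR genes rose (median 0.43, adjusted p = 0.00051, and adjusted p = 0.44 with an estimated correlation), 14 of 24 higher and 1 lower, or 16 and 1 adjusted over the list alone. Those that led were the insulin receptor substrate Irs2 (1.37, adjusted p = 0.00054), the kinase Mtor (0.56, adjusted p = 0.00085) and its inhibitor Tsc1 (0.43, adjusted p = 0.0016). The median of this list was 0.25 with a lane 2 term, where 3 members were higher, and 0.16 without lane 2 libraries. Igf1 stood at -0.31 ± 0.25, adjusted p = 0.36, Mstn, the myostatin gene, at 0.41 ± 0.16, adjusted p = 0.056, and Cdkn1a at 0.83 ± 0.40, adjusted p = 0.11, and these did not pass, though Cdkn1a did without PBS replicate 1 (1.11).

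**Figure D2:**
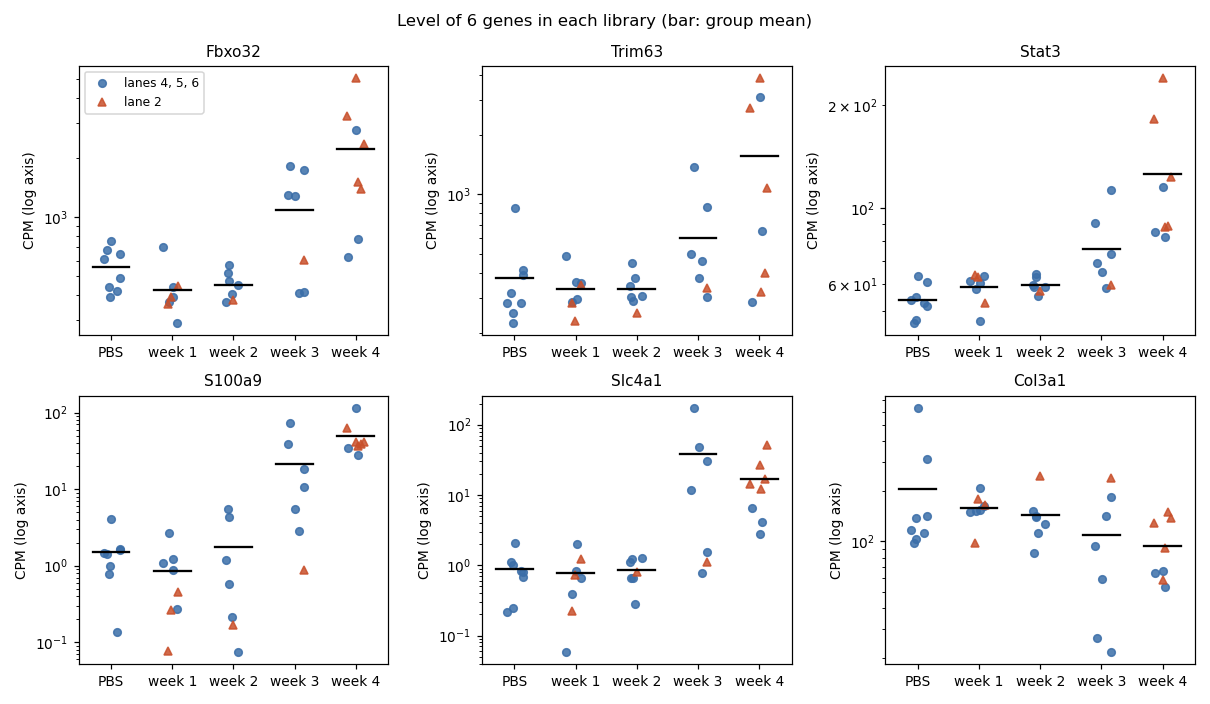
Level of 6 genes in each library, in CPM on a log axis, by group, with triangles for lane 2, circles for the other lanes and a bar for the group mean. At week 4 Fbxo32, Stat3, S100a9 and Slc4a1 lie above the PBS mean in 8 of 8 libraries, and Trim63 in 6.

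Inflammatory genes rose at week 4. Stat3, the transcription factor downstream of IL-6, rose 2.33-fold (1.22 ± 0.16, adjusted p = 3.0e-06), in 8 of 8 libraries, and was at 0.81, adjusted p = 0.0015 without lane 2. Genes of the IL-6, STAT3 and acute phase list rose (median 1.21, adjusted p = 1.3e-07, and adjusted p = 0.45 with an estimated correlation), 13 of 19 over all genes and 13 adjusted over the list alone, with a median of 0.71 without lane 2 libraries. Osmr (1.63, adjusted p = 4.8e-08), the acute phase glycoprotein Lrg1 (1.35, adjusted p = 3.9e-05) and the iron-binding lipocalin Lcn2, which rose 13.7-fold (3.78 ± 0.63, adjusted p = 9.2e-05), led them. The feedback inhibitor Socs3 stood at 0.85 ± 0.48, adjusted p = 0.18, and passed at 1.66 without PBS replicate 6, which held 31.0 CPM. Csf2rb and Csf2rb2, receptor subunits for GM-CSF and IL-3, rose 6.78-fold and 6.09-fold (2.76 ± 0.34, adjusted p = 6.3e-07, and 2.61 ± 0.29, adjusted p = 9.2e-08). These are paralogs of close sequence, which counting could split unevenly. The protease inhibitor Serpina3n rose 5.88-fold (2.56 ± 0.59, adjusted p = 0.0022). Without PBS replicate 1 Lcn2 was at 4.67 and Serpina3n at 3.20.

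Neutrophil markers had the highest median of the lists at week 4 (median 4.51, adjusted p = 2.0e-14, and adjusted p = 0.36 with an estimated correlation), and 12 of 13 rose, as many as when adjusted over the list alone. S100a9 rose 31.4-fold, to 49.7 ± 28.5 CPM (SD, 4.97 ± 0.70, adjusted p = 7.2e-06), and S100a8 30.0-fold (4.91 ± 0.72, adjusted p = 1.5e-05). Ltf and Ngp, proteins of neutrophil granules, stood at 7.77 and 7.50 (adjusted p = 5.5e-08 and 3.1e-07), or at 9.37 and 8.14 without PBS replicate 4. Erythroid markers rose (median 1.28, adjusted p = 0.0032, and adjusted p = 0.66 with an estimated correlation), 4 of 7 over all genes and 6 adjusted over the list alone. Their median was 0.79 without lane 2 libraries, and that of endothelial markers 0.25. Slc4a1 was at 4.23 ± 0.80, adjusted p = 0.00039. Tent5c, a poly(A) polymerase (2.54 ± 0.53, adjusted p = 0.00099), and Apol11b (3.41 ± 0.76, adjusted p = 0.0017) were among the 10 largest rises of called genes of at least 5 CPM on average, predicted-gene names left out. Endothelial markers rose (median 0.43, adjusted p = 9.5e-05, and adjusted p = 0.38 with an estimated correlation), 8 of 13 over all genes and 9 adjusted over the list alone, with Vwf at 1.35, adjusted p = 3.4e-07 and the adhesion molecule Pecam1 at 0.87, adjusted p = 3.4e-07. Macrophage markers did not pass (median 0.0073, adjusted p = 0.11), with a mean of -0.029 and an upward test, but passed as higher without PBS replicate 1 (0.74, adjusted p = 3.0e-07). The scavenger receptor Cd163 rose (1.08, adjusted p = 0.0056). Ctss was called lower (-1.20, adjusted p = 0.048), but it was at 0.46 with DESeq2 and at 0.46 without PBS replicate 1.

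**Figure D3:**
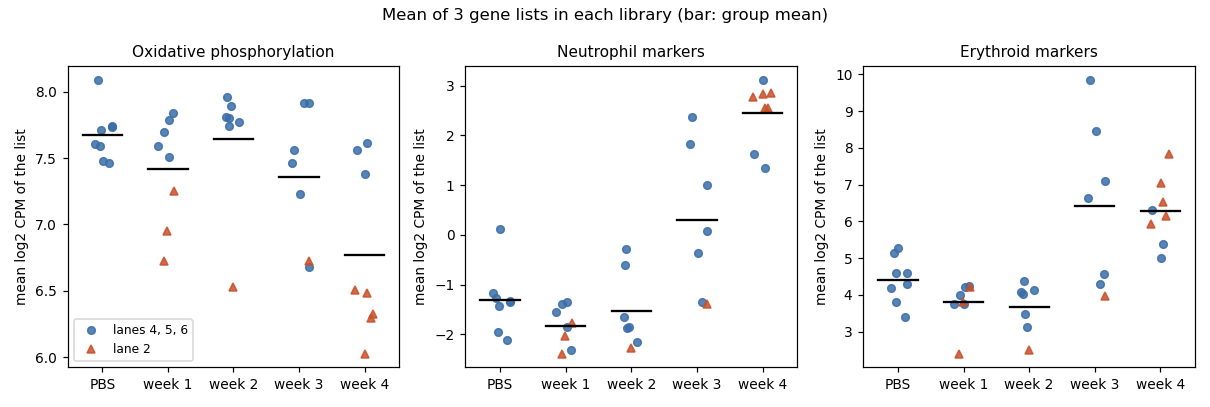
Mean log2 CPM of 3 gene lists in each library, by group, with triangles for lane 2, circles for the other lanes and a bar for the group mean. Oxidative phosphorylation genes lie lower on average in lane 2 libraries than in the others of each of weeks 1 to 4, and neutrophil markers at week 4 average 2.71 in lane 2 and 2.04 in other lanes, against -1.31 in PBS.

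Some lists of energy metabolism were called lower at week 4, but not all. Of the 76 nuclear genes of oxidative phosphorylation, 69 fell and 0 rose (74 fell adjusted over the list alone), with a median of -0.75, adjusted p = 4.8e-22, and adjusted p = 0.64 with an estimated correlation. Cox5b, a subunit of cytochrome c oxidase, fell (-1.29 ± 0.29, adjusted p = 0.0018), as did Uqcrfs1, the Rieske protein of complex III (-1.17, adjusted p = 0.0023), and Atp5c1 of ATP synthase (-0.84, adjusted p = 0.0023). The list is also lower in lane 2 within weeks 1 to 3. Its median was -0.29, adjusted p = 3.6e-10 with a lane 2 term, where 1 member passed. Without lane 2 libraries it was -0.16, adjusted p = 5.3e-05, but the list mean did not pass (exact permutation p = 0.25). Mitochondrially encoded genes fell (median -0.51, adjusted p = 0.0042, and adjusted p = 0.66 with an estimated correlation), 4 of 13 over all genes and 4 adjusted over the list alone, led by mt-Nd1 (-0.51, adjusted p = 0.0067). Their reads can be shared with nuclear copies, and the list mean ranged from 8.01 to 12.7 log2 CPM within week 4 and from 9.42 to 13.4 within PBS. Glycolysis and glycogen genes fell (median -0.40, adjusted p = 0.017, and adjusted p = 0.66 with an estimated correlation), 11 of 27 lower and 1 higher, the same adjusted over the list alone, with the enolase Eno3 at -0.91, adjusted p = 0.0093 and the kinase gene Pkm at -0.48, adjusted p = 0.0056. Without lane 2 this call ended (-0.18, adjusted p = 0.16). Ppargc1a, a coactivator of mitochondrial genes, stood at 0.16 ± 0.13, adjusted p = 0.37.

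Some matrix and tendon genes also lay lower at week 4. Col1a1 and Col3a1, the main fibrillar collagens, fell 2.22-fold and 2.20-fold (-1.15 ± 0.40, adjusted p = 0.03, and -1.14 ± 0.39, adjusted p = 0.025). Without PBS replicate 1 they were at -0.79 and -0.64, and both calls ended. The extracellular matrix list did not pass over all libraries (median -0.35, adjusted p = 0.15), with 5 of 37 lower and 4 higher, or 4 and 4 adjusted over the list alone. It passed with a lane 2 term (-0.55, adjusted p = 4.7e-06), where 10 members were lower, and without lane 2 libraries (-0.72, adjusted p = 1.3e-11). Loxl2, a collagen cross-linking enzyme, fell (-1.18, adjusted p = 0.00063), and the basement membrane collagens Col4a1 (0.60, adjusted p = 0.018) and Col4a2 (0.67, adjusted p = 0.004) rose. Tendon markers fell (median -0.86, adjusted p = 0.024, and adjusted p = 0.66 with an estimated correlation), 3 of 9 over all genes and 4 adjusted over the list alone, and their median was -1.69 with a lane 2 term and -2.29 without lane 2 libraries. This list was called in 12 of 16 fits with 1 library left out, and its median was -0.38 without PBS replicate 3. Interferon response genes fell (median -0.28, adjusted p = 0.031, and adjusted p = 0.67 with an estimated correlation), 12 of 40 lower and 3 higher, the same adjusted over the list alone, led by Psmb10, a subunit of the immunoproteasome (-0.87, adjusted p = 0.00069). This call ended under a lane 2 term (-0.13, adjusted p = 0.11), without lane 2 libraries (-0.14, adjusted p = 0.17) and without PBS replicate 1 (-0.22, adjusted p = 0.12), and it held in 10 of 16 fits with 1 library left out.

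The largest falls among genes of at least 5 CPM held osteopontin, Spp1 (-2.99 ± 0.63, adjusted p = 0.0011), whose value without PBS replicate 1 was -0.67. They also held the transferrin receptor Tfrc (-1.49 ± 0.29, adjusted p = 0.00056), the muscle-secreted peptide Ostn (-1.74 ± 0.41, adjusted p = 0.0025), neuronatin, Nnat (-1.57 ± 0.51, adjusted p = 0.02), whose call ended without PBS replicate 7 (-1.24), and Crip1 (-1.46 ± 0.46, adjusted p = 0.016). Foxo6os (-1.88 ± 0.46, adjusted p = 0.0036) is antisense to Foxo6, and the sources used here do not state a strand setting for the counts. Ndufab1-ps (-2.61, adjusted p = 0.0048) and Rps12-ps9 (-2.50, adjusted p = 0.015) are pseudogenes whose reads can be shared with their parents, and Rn7sk (-3.02 ± 1.09, adjusted p = 0.034) encodes a small nuclear RNA. Rn7sk was at 0.026 with a term for every lane, and its call held in 9 of 16 fits with 1 library left out. Spp1, Tfrc, Ostn and Foxo6os also passed with a lane 2 term (adjusted p = 0.019, 0.0058, 0.03 and 0.024), and the others named in this paragraph did not.

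Of the other lists, muscle fibre genes did not pass at week 4, with fast fibre genes at median -0.39, adjusted p = 0.16 and slow ones at median -0.26, adjusted p = 0.59. Myh4 was at 0.15 ± 0.20, adjusted p = 0.59 and Myh7 at 0.21 ± 0.31, adjusted p = 0.64. Nor did fibro-adipogenic markers (median -0.24, adjusted p = 0.051), adipocyte markers (median -0.40, adjusted p = 0.12), T, B and NK cell markers (median -0.53, adjusted p = 0.27), pericyte and smooth muscle markers (median -0.13, adjusted p = 0.70) and Schwann cell markers (median -0.081, adjusted p = 0.76). Satellite cell genes (median 0.19, adjusted p = 0.19), denervation genes (median 0.19, adjusted p = 0.36), cell cycle genes (median -0.44, adjusted p = 0.23), clock genes (median 0.052, adjusted p = 0.29) and myostatin and activin genes (median 0.13, adjusted p = 0.35) did not pass either. The same held for endoplasmic reticulum stress (median 0.16, adjusted p = 0.15), heat shock (median 0.30, adjusted p = 0.24), polyamine (median -0.17, adjusted p = 0.18), fatty acid (median -0.11, adjusted p = 0.40) and mitochondrial biogenesis genes (median 0.013, adjusted p = 0.72, with a downward test). Antioxidant genes (median -0.099, adjusted p = 0.75) had a mean of 0.11 and an upward test. Single members still passed, among them Musk, a kinase of the neuromuscular junction (1.33, adjusted p = 0.00083), the receptor Notch1 (1.01, adjusted p = 0.00025), the spermine oxidase Smox (-1.45, adjusted p = 0.0047) and the lipid droplet protein Plin4 (1.13, adjusted p = 0.0005). Fast fibre, antioxidant, heat shock and fibro-adipogenic lists passed with a lane 2 term (adjusted p = 0.041, 0.023, 0.036 and 0.019), and the last also without lane 2 libraries (-0.60, adjusted p = 0.0066).

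**Figure D4:**
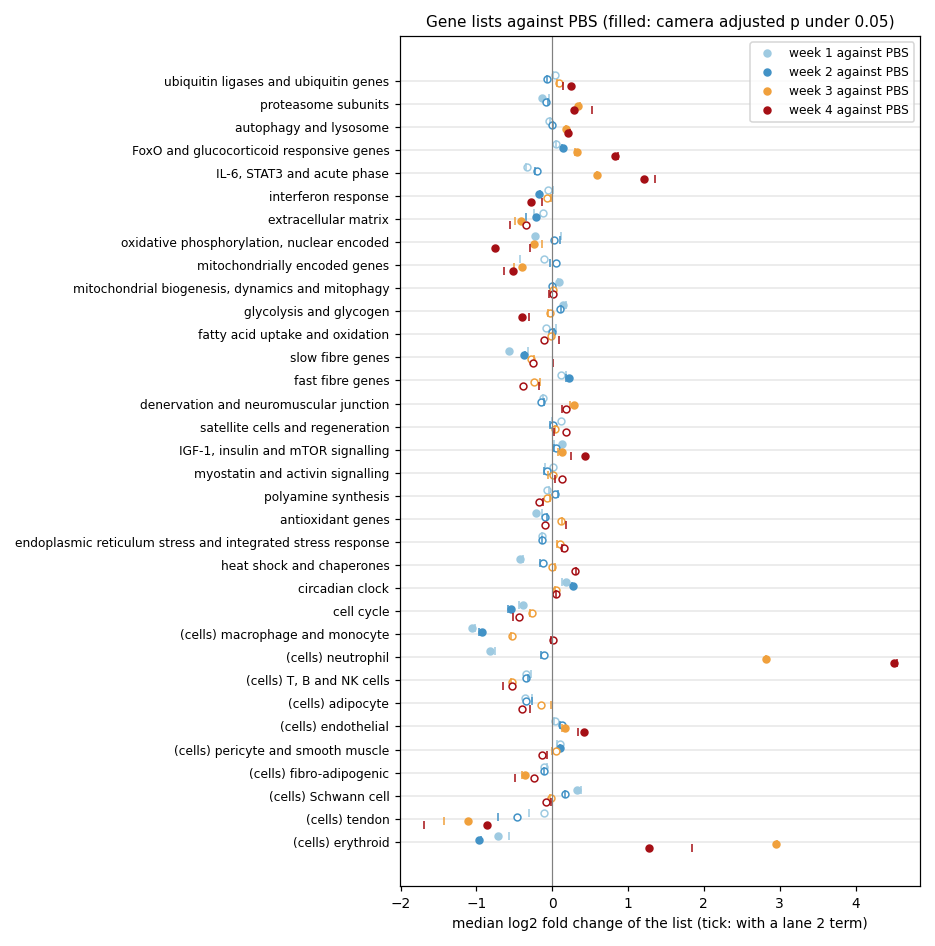
Median log2 fold change of each of the 34 gene lists against PBS at weeks 1 to 4, filled where the camera test with a preset correlation of 0.01 had an adjusted p under 0.05, with a tick for the median under a lane 2 term. Neutrophil markers reach 4.51 and oxidative phosphorylation genes -0.75 at week 4, where the tick of the latter stands at -0.29.

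In all, edgeR called 4315 genes at week 4, 2244 higher and 2071 lower, of which 345 rose and 302 fell at least 2-fold. With a lane 2 term there were 829, 749 of them among the 4315, with 506 higher and 323 lower. Without lane 2 libraries there were 136 (112 higher), and with a term for every lane 93.

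Weeks of tumour were also compared with one another. Week 4 (n = 8) differed from week 3 (n = 7) in 516 genes, 334 of them higher. Csf2rb rose 3.25-fold (1.70 ± 0.34, adjusted p = 0.0064). Other rises were the zinc transporter Slc39a14 (1.65 ± 0.40, adjusted p = 0.021), the nuclear receptor Nr4a3 (2.19 ± 0.62, adjusted p = 0.043) and the mitochondrial tRNA genes mt-Ty (3.19 ± 0.77, adjusted p = 0.021) and mt-Tn (2.85 ± 0.57, adjusted p = 0.0064). Slc39a14 was at 0.78 without week 4 replicate 5 and Nr4a3 at 1.504 without week 4 replicate 4, and they were called in 11 of 15 and 8 of 15 fits with 1 library left out. Stat3 rose between these weeks (0.73, adjusted p = 0.018), while Fbxo32 (1.04, adjusted p = 0.06), Trim63 (1.37, adjusted p = 0.059) and Slc4a1 (-1.18, adjusted p = 0.26) did not pass. The largest falls called were Rn7sk (-5.09 ± 1.17, adjusted p = 0.018), Mir6236 (-3.90 ± 1.09, adjusted p = 0.04), Lars2, a mitochondrial tRNA synthetase gene (-3.87 ± 0.99, adjusted p = 0.029), Krt80 (-3.23 ± 0.85, adjusted p = 0.033) and Gpnmb (-2.83 ± 0.83, adjusted p = 0.048). Week 3 replicate 3 held 393 CPM of Rn7sk, 3163 of Mir6236 and 14791 of Lars2, and without it these were at -3.04, -1.99 and -1.54 and did not pass, and neither did mt-Ty. Krt80 and Gpnmb went to 0.89 and 0.54 without week 3 replicate 1. DESeq2 gave Krt80 and Gpnmb the opposite sign (0.95 and 0.58), and in week 3 each of these 5 genes had an SD above its mean. With a lane 2 term 26 genes passed, without lane 2 libraries 0 (837 at an unadjusted p under 0.05), and with DESeq2 1005.

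In the other comparisons between weeks, genes outside those always named were picked after their values were seen. Week 3 differed from week 2 in 63 genes, all higher, among them Slc4a1 (5.47, adjusted p = 0.00082), Alas2 (3.92, adjusted p = 0.00073), S100a8 (3.98, adjusted p = 0.0046) and Lcn2 (3.04, adjusted p = 0.026). A lane 2 term gave 66 and the fit without lane 2 libraries 41. Week 3 differed from week 1 in 155 genes, 147 of them higher, with Fbxo32 (1.35, adjusted p = 0.023), Csrp3 (2.04, adjusted p = 0.0012) and S100a9 (4.59, adjusted p = 0.0006) among the rises. A lane 2 term gave 139 and the fit without lane 2 libraries 102. Week 2 differed from week 1 in 7 genes, all lower, which were the mitochondrial copies of week 1 replicate 7. A lane 2 term gave 0 (444 at an unadjusted p under 0.05), and DESeq2 0.

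Week 4 differed from week 1 in 3321 genes, 1896 of them higher, and from week 2 in 3471, 1985 of them higher. Fbxo32 rose against both (2.38, adjusted p = 4.0e-06, and 2.29, adjusted p = 3.0e-05), and so did Trim63 (2.23, adjusted p = 0.00039, and 2.23, adjusted p = 0.00092), Stat3 (1.10, adjusted p = 1.5e-05, and 1.08, adjusted p = 6.5e-05) and Socs3 (1.86, adjusted p = 0.0086, and 1.77, adjusted p = 0.015). Cdkn1a, an inhibitor of the cell cycle, rose as well (1.49, adjusted p = 0.0097, and 1.66, adjusted p = 0.0073). Cox5b fell against both (-0.85, adjusted p = 0.03, and -1.26, adjusted p = 0.0037). With a lane 2 term 3160 and 1590 genes passed, of which 2789 and 1423 were also called over all libraries by group. Without lane 2 libraries there were 90 and 59.

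Genes called at week 4 were then followed at earlier weeks, with odd-numbered PBS libraries for the call and even-numbered ones for the earlier weeks. The 1057 higher genes had median log2 fold changes of 0.11 at week 1, 0.095 at week 2 and 0.21 at week 3. The 879 lower genes had medians of -0.12, -0.077 and -0.20. By limma's fry test, with a threshold of 0.05 before adjustment, the higher genes passed as a set at week 3 only, and adjustment over the 6 tests ended that call (adjusted p = 0.22). With odd and even PBS libraries exchanged they did not pass (median 0.18, adjusted p = 0.39). The lower genes did not pass at any of these weeks (adjusted p = 0.22 at week 3). A term for every lane, fixed before the data were examined, left 16 higher genes, whose median at week 3 was 0.97 (adjusted p = 0.0018), and 1 lower gene. Under a lane 2 term, which was chosen after the data were examined and left 126 higher and 84 lower genes, the higher ones had a median of 0.48 at week 3 (adjusted p = 0.00084) and the lower ones -0.28 (adjusted p = 0.11). In both fits with a lane term, the lane differences are estimated in part from week 3 libraries. They enter the call at week 4 and the values at week 3, so the 2 sides are not separate there.

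The authors' deposited table for week 4 against PBS listed 4313 genes. Of the 4157 tested here, 4142 had the same sign and 3786 were also called. The authors' deposited tables listed 44 genes for week 1, 100 for week 2 and 22 for week 3 against PBS, and of these 1, 0 and 13 were called here. Between weeks the authors' deposited tables listed 476 genes for week 4 against week 3, 116 for week 3 against week 1, 1 for week 3 against week 2, 3336 for week 4 against week 1 and 3388 for week 4 against week 2. Of these, 300, 69, 0, 2835 and 2847 were called here with the same sign.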

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

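The tests of lane 2 as part of the cause, of the mitochondrial copies and of the blood cell markers, the set of 4 libraries of unusual read assignment with its bound of 8%, the division into lane 2 and other lanes, and the macrophage and cell cycle means of PBS replicate 1 were chosen only after the result was seen. The other tests of this part were not.

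Some libraries lay apart from the rest of their group by Dixon's rule. It was run on the 13 always-named genes, 3 read measures and 8 gene lists in each of the 5 groups, 120 tests, of which 23 passed, and chance marks about 1 in 20 groups. In PBS replicate 1, Trim63 was at 849 CPM, Cdkn1a at 55.2 and Col3a1 at 633, and mean log2 CPM was 6.27 for FoxO and glucocorticoid genes, 3.50 for IL-6 and STAT3 genes and 0.11 for neutrophil markers, all above the other PBS libraries. Outside these tests it also lay above them in mean log2 CPM of macrophage markers (5.31, against 1.92 to 3.21) and cell cycle genes (3.13, against 0.76 to 1.58). Week 2 replicate 3, of lane 2, had Myh4 at 88668 CPM and Col3a1 at 247, with lists at 6.53 for oxidative phosphorylation, 6.29 for proteasome and 5.58 for extracellular matrix. At other libraries, Fbxo32 stood at 701 CPM in week 1 replicate 2, Foxo1 at 61.7 in week 3 replicate 6, Cdkn1a at 87.4 in week 3 replicate 1, Igf1 at 44.6 in week 4 replicate 7, Socs3 at 31.0 in PBS replicate 6 and Ppargc1a at 59.9 in week 4 replicate 5. List means stood out at 6.17 for FoxO genes in week 2 replicate 5, 8.09 for oxidative phosphorylation in PBS replicate 5 and 2.40 for erythroid markers in week 1 replicate 5. Reads in genes numbered 24.8 M in week 1 replicate 6 and 13.4 M in week 4 replicate 5, and the share of reads in genes was 48.7% in week 2 replicate 6.

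Weeks of tumour were compared with one another by direct test. Genes differing numbered 7 for week 2 against week 1, which were the mitochondrial copies of week 1 replicate 7, 63 for week 3 against week 2, 516 for week 4 against week 3, 155 for week 3 against week 1, 3321 for week 4 against week 1 and 3471 for week 4 against week 2. For week 2 against week 1 and week 4 against week 3, chance is not excluded.

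Reads outside the gene counts were more frequent in some tumour libraries than in any PBS library. Reads in no gene made up 8.97% in week 3 replicate 1, 10.6% in week 3 replicate 3 and 10.1% in week 2 replicate 6, against at most 6.10% in PBS. Reads over more than 1 gene made up 10.6% in week 3 replicate 3 and 11.0% in week 2 replicate 6, against at most 5.23%.

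Chance was weighed for each count by other splits of the same libraries, 100 per count with the real one included. The share of splits as large was under 0.05 for week 3 against PBS (51 genes, highest other 207, 4 of 100 splits as large) and week 4 against PBS (4315, 624, 1 of 100). A term for every lane called 0 and 93 in these, and the lanes that hold both groups called 0 for week 3. Between weeks the share was under 0.05 for week 3 against week 2 (63, 58, 1 of 100), week 3 against week 1 (155, 289, 2 of 100), week 4 against week 1 (3321, 998, 1 of 100) and week 4 against week 2 (3471, 439, 1 of 100). The same holds for the 5 groups together (3219, 451, 1 of 100). These shares are not adjusted over the counts. The splits took no account of lane, so a low share cannot tell group from lane. Week 4 and PBS shared no lane. Chance cannot be excluded for week 1 against PBS (9, 9, 6 of 100), week 2 against PBS (0, 1, 100 of 100), week 2 against week 1 (7, 11, 75 of 100) and week 4 against week 3 (516, 3443, 6 of 100). For week 3 against PBS and week 4 against week 3, the highest other split called several times the real count, and what that split separates was not tested.

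The lower oxidative phosphorylation genes of week 4 stand where 5 of 8 libraries come from lane 2 and PBS has none there. Within weeks 1 to 3, the list mean was lower in lane 2 (difference -0.91 log2, exact permutation p = 0.00073), and outside lane 2 the week 4 median was -0.16 rather than -0.75, so lane 2 could account for part of the fall. Within lane 2 week 4 lay below week 1 (difference -0.65, exact permutation p = 0.018), which argues against lane 2 as the whole cause. Outside lane 2 the same difference was -0.17 (exact permutation p = 0.16). The single lane 2 libraries of weeks 2 and 3 had list means of 6.53 and 6.73, near the 6.33 ± 0.19 (SD) of week 4 in lane 2. Week 2 outside lane 2 was at 7.83. The argument thus rests on week 1, and lane 2 as the whole cause is not excluded. The list also fell further than lists matched on transcript length and expression. Its median lay at percentile 0 of 10000 lists matched on median transcript length, whose median was -0.096 and middle 95% ran from -0.21 to 0.026. Matched on the longest transcript these were -0.33 and -0.42 to -0.19. Genes of matched lists were drawn singly and need not vary together, so the percentile cannot tell whether length is part of the cause. Within weeks 1 to 3, 1154 genes with transcripts under 1000 bases were lower in lane 2 and 431 higher, against 81 and 553 over 3000 bases. Week 4 of tumour stays open for the remainder, since outside lane 2 the list mean differed from PBS by -0.16 (exact permutation p = 0.25, 3 libraries).

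The 7 mitochondrial copies higher at week 1 were called on the reads of replicate 7, with 0 called without it. There the copies summed to 63345 CPM, against 12.4 to 139.9 in the other 37 libraries. Copies and mitochondrial genes together came to 166037 CPM, within the 77199 to 219980 of the others, so reads of mitochondrial transcripts placed on near-identical nuclear copies could be the source. Whether 1 week of tumour adds to them cannot be told apart from no effect: in the 7 other week 1 libraries the copies differed from PBS by 0.44 log2 (exact permutation p = 0.42).

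Neutrophil and erythroid genes rose at weeks 3 and 4, and blood left in the muscle is a technical candidate. The tables argue against more blood of unchanged make-up at week 4, since the neutrophil list mean minus the erythroid one differed from PBS by 1.91 (exact permutation p = 0.00016) and from week 3 by 2.29 (exact permutation p = 0.0011). The comparison with PBS takes the PBS level of both lists as blood, which was not tested. From week 3 to week 4 the neutrophil mean went from 0.31 to 2.46 and the erythroid one from 6.42 to 6.27. At week 3 it differed from PBS by -0.38 (exact permutation p = 0.54), so more blood at week 3 stays open. Lane 2 is argued against, since outside it the erythroid list at week 3 lay above PBS by 2.42 (exact permutation p = 0.008) and the neutrophil list by 1.90 (exact permutation p = 0.0057). Blood of changed make-up and neutrophils within the muscle stay open, and neither was tested.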

How the results depend on the processing

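Lane 2 as a term, the lane 2 libraries left out, lanes 2 and 4 alone with a lane term, the 4 libraries of unusual read assignment left out, and each library left out for the gene lists are settings chosen only after the result was seen, and the others were planned.

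Counts under RLE and upper quartile size factors stayed within 1.5 times of the reported ones in all 10 comparisons. The values below did not. Sequencing lane and group overlap, so where a lane term or the loss of lane 2 lowers a count, effect and lane cannot be told apart. A term for every lane gave 0 at week 1 against PBS, 0 at week 3 against PBS, 93 at week 4 against PBS, 0 at week 2 against week 1, 2 at week 4 against week 3, 44 at week 3 against week 1, 1106 at week 4 against week 2 and 713 among the 5 groups. A lane 2 term gave 829 at week 4 against PBS, 0 at week 2 against week 1, 26 at week 4 against week 3, 1590 at week 4 against week 2 and 1646 among the 5 groups. Fewer libraries remain without lane 2, and the counts were 95 at week 3 against PBS, 136 at week 4 against PBS, 41 at week 3 against week 2, 0 at week 4 against week 3, 102 at week 3 against week 1, 90 at week 4 against week 1, 59 at week 4 against week 2 and 244 among the 5 groups. Only lanes that hold both groups, with fewer libraries again, gave 0 at week 1 against PBS and 0 at week 3 against PBS. Lanes 2 and 4 alone with a lane term gave 0 at week 4 against week 3, 1655 at week 4 against week 1 and 80 at week 4 against week 2. The 4 libraries of unusual read assignment left out gave 0 at week 1 against PBS, 0 at week 2 against week 1, 35 at week 3 against week 2, 22 at week 4 against week 3 and 60 at week 3 against week 1. With these left out and a lane 2 term, counts were 0 at week 1 against PBS, 1188 at week 4 against PBS, 0 at week 2 against week 1, 35 at week 3 against week 2, 1 at week 4 against week 3, 51 at week 3 against week 1, 1815 at week 4 against week 2 and 1666 among the 5 groups.

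DESeq2 called 1 at week 1 against PBS, 1 at week 2 against PBS, 120 at week 3 against PBS, 0 at week 2 against week 1, 112 at week 3 against week 2, 1005 at week 4 against week 3 and 272 at week 3 against week 1. Limma voom with quality weights called 0 at week 1 against PBS, 11 at week 2 against PBS, 31 at week 3 against PBS, 0 at week 2 against week 1, 17 at week 3 against week 2, 3704 at week 4 against week 3, 62 at week 3 against week 1, 5450 at week 4 against week 1 and 6477 at week 4 against week 2. Only the 2 groups compared, with fewer libraries for the spread, gave 0 at week 1 against PBS, 0 at week 3 against PBS, 0 at week 2 against week 1, 0 at week 3 against week 2, 4 at week 4 against week 3 and 3 at week 3 against week 1. No low-count filter gave 1 at week 2 against PBS and 237 at week 4 against week 3, and a mean of at least 5 CPM, which tests fewer genes, 24 at week 3 against PBS, 31 at week 3 against week 2 and 84 at week 3 against week 1. A change of at least 1.5 times, which only adds a threshold, left 2013 at week 4 against PBS, 261 at week 4 against week 3, 1600 at week 4 against week 1 and 1767 at week 4 against week 2. For the tools and filters that raised or lowered counts, the cause was not tested.

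Leaving out 1 library at a time gave these ranges of genes changed, week 1 against PBS 0 to 10 (0 without week 1 replicate 7), week 2 against PBS 0 to 0, week 3 against PBS 12 to 104 (81 without week 3 replicate 3, 103 without week 3 replicate 4, 89 without PBS replicate 1, 12 without week 3 replicate 6, 104 without week 3 replicate 8), week 4 against PBS 3043 to 5174, week 2 against week 1 0 to 7 (0 without week 1 replicate 7 and 0 without any of the 7 of week 2), week 3 against week 2 29 to 120 (39 without week 3 replicate 1, 106 without week 3 replicate 3, 120 without week 3 replicate 4, 29 without week 3 replicate 6, 100 without week 3 replicate 8, 40 without week 2 replicate 6, 39 without week 2 replicate 7), genes changed, week 4 against week 3, 95 to 1782 (147 without week 4 replicate 3, 95 without week 4 replicate 4, 101 without week 4 replicate 5, 992 without week 3 replicate 1, 138 without week 3 replicate 3, 139 without week 3 replicate 4, 1782 without week 4 replicate 7, 1486 without week 4 replicate 8, 263 without week 3 replicate 5, 1264 without week 3 replicate 8), week 3 against week 1 76 to 473 (76 without week 3 replicate 1, 298 without week 3 replicate 4, 103 without week 3 replicate 6, 473 without week 3 replicate 8), week 4 against week 1 1940 to 4263 (1940 without week 4 replicate 5), week 4 against week 2 2051 to 4476 (2051 without week 4 replicate 5). No gene count of week 2 against PBS moved.

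All lists called at the preset correlation, 14, 10, 14 and 14 at weeks 1 to 4 against PBS, became 0 at week 1, 0 at week 2, 0 at week 3 and 0 at week 4 with an estimated correlation, and without lane 2 libraries 9 were called at week 1. With each library left out in turn, lists called numbered 10 to 15 at week 1, 3 to 13 at week 2, 12 to 17 at week 3, 12 to 17 at week 4. The 3 of week 2 are those without PBS replicate 1, which lies high in macrophage and cell cycle genes. The oxidative phosphorylation list at week 1 reversed to 0.11 with a term for every lane, 0.11 with a lane 2 term and 0.018 without lane 2 libraries. Fry called 2 lists at week 1, 0 at week 2, 2 at week 3 and 11 at week 4, of which 2, 0, 2 and 9 were also called by camera. Oxidative phosphorylation had an adjusted p of 0.55 at week 1 and 0.42 at week 3 by fry. At week 4 the neutrophil list had 3.0e-06 and oxidative phosphorylation 0.0099.

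Single genes reversed as well. Rn7sk at week 4 against PBS went to 0.026 with a term for every lane. Krt80 and Gpnmb at week 4 against week 3 went to 0.95 and 0.58 with DESeq2, and to 0.69 and 0.39 without the 4 libraries. Ankrd1 and Oaz1 at week 4 against PBS went to -0.30 and 0.023 without lane 2 libraries, and Top2a and Ctss to 0.66 and 0.46 with DESeq2, and the cause was not tested. Top2a and Ctss went to 0.69 and 0.46 without PBS replicate 1. Of the other named gene results, 510 kept their side of the threshold with a lane 2 term and 91 lost their call. With a term for every lane 451 kept theirs and 149 lost their call. Without lane 2 libraries 471 kept theirs, 126 lost and 2 gained a call, and with DESeq2 589 kept theirs, 2 lost and 6 gained a call. Direction was compared only for results called in at least 1 of the 2 fits.

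Among week 4 genes at earlier weeks, the higher genes at week 3 had a median of 0.18 and lost their call before adjustment with odd and even PBS libraries exchanged. The lower genes at week 3 had -0.28 and gained it with a lane 2 term. No paired analysis was possible because the labels share no number between groups. At the depth and number of libraries of week 4 against PBS, with the trend of spread fitted to all groups, 37.3% of simulated 1.5-fold changes were recovered.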

Other observations

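The genes and values of this part were chosen only after the result was seen, and most of the genes stand outside the rule for named genes.

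Some further genes passed at both week 3 and week 4. Selp, which encodes the P-selectin that endothelium and platelets display to leukocytes, rose at week 3 (1.29 ± 0.26, adjusted p = 0.0086) and week 4 (2.46 ± 0.25, adjusted p = 4.8e-08). Sele, the E-selectin of activated endothelium, rose at both (2.75, adjusted p = 0.035, and 3.55, adjusted p = 0.00011), from a level under 1 CPM. Jak3, a kinase of cytokine receptors, rose at both (0.68 ± 0.14, adjusted p = 0.013, and 1.28 ± 0.14, adjusted p = 4.8e-08), and so did Il1b, the interleukin 1 beta gene (2.82, adjusted p = 0.01, and 3.58, adjusted p = 3.4e-05). Jun, a part of the AP-1 transcription factor, rose at both (0.82 ± 0.18, adjusted p = 0.019, and 0.89 ± 0.17, adjusted p = 0.00048). Acer2, an alkaline ceramidase (1.51 ± 0.33, adjusted p = 0.02, and 2.47 ± 0.33, adjusted p = 2.5e-06), and Galnt15, a glycosyltransferase (0.88 ± 0.19, adjusted p = 0.015, and 1.56 ± 0.18, adjusted p = 3.3e-07), followed the same course.

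Week 3 libraries differed widely in blood cell markers. Slc4a1 was at 30.6, 1.54, 0.769, 47.5, 174, 11.6 and 1.12 CPM in replicates 1, 3, 4, 5, 6, 7 and 8. S100a9 was at 18.5, 10.8, 2.82, 5.48, 73.1, 39.0 and 0.882 CPM in the same order. The SD of the erythroid list mean was 2.25 log2 at week 3, against 0.64 in PBS and 0.89 at week 4.

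The mitochondrial gene mt-Co3, which has near-identical nuclear copies, ranged from 7.93 CPM in week 4 replicate 3 to 24067 CPM in PBS replicate 5. The sum of mitochondrial genes and copies ranged from 77199 to 219980 CPM over all libraries.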
